A study of Mus musculus with 7 samples.

How the data were processed

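Total RNA of frozen livers from 3 wild-type and 4 miR-122 knockout mice of 2 months was labelled with biotin and hybridised to Affymetrix mouse arrays, per the labels' protocols. The genotype and the animal's number came from the sample titles, and the numbers do not recur between genotypes, so no pairing was used. The labels name no sex, litter, batch or scan date. The p-values of single genes are set against the spread between these animals.

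The deposited table holds 1 log2 value per probe set and array, made by the authors with RMA in Partek software, per the series' design text and the submitters' processing notes. RMA corrects background, quantile normalizes across arrays and summarises probes on the log2 scale. Versions and probe set definitions are not given in the sources used here. The values lay between 2.204 and 14.887, with 0 missing values and 0 pairs of identical arrays. No counts lie behind array values, so no depth was computed.

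Of 45101 probe sets, 64 were control probe sets. Platform annotation gave 1 gene symbol for 34958 probe sets and several for 932, and 9211 were not listed and stay unnamed here. Of the probe sets with 1 symbol, 34741 had an Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, which updated 0 symbols. The files name no genome build, so no coordinates are given. For each of 18193 genes, of which 9010 had more than 1 probe set, the probe set with the highest mean over the 7 arrays was used. Knockout arrays enter that mean, so the rule can favour a probe set that is higher in knockout over one that is not.

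Knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates) on the log2 values, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are knockout minus wild type. The fit had 5 residual and 3.99 prior degrees of freedom. Before the data were examined, 31 gene lists with 569 entries were written down, and 52 entries were not measured. The 30 lists with at least 5 measured genes were tested with limma's camera (preset correlation 0.01), which compares a list with all other genes. With that preset, its p-values do not take in how strongly a list's genes vary together between these animals. Camera with an estimated correlation, its rank version and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were alternatives. The mean of each list per array was also compared by an exact two-sided permutation test over the 35 splits of the 7 arrays into 4 and 3. That test was chosen after the list results were seen. The floor for levels, the highest of 27 Bacillus subtilis control probe sets on each array, was also chosen after the data were seen. The dimmer genotype's arrays were raised to it before means were compared, and whether such controls were added to the samples is not known here.

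Genes are named by a rule written before the data were examined: the 10 largest rises and 10 largest falls among called genes whose knockout arrays all lay on one side of the wild-type arrays, without predicted symbols, the 4 members of each list with the smallest p, and Afp, Igf2, H19, Aldoa, Mttp, Klf6, Cd36, Alb, Xist and Ddx3y. No probe set used here named H19 or Ddx3y alone. Ccn2, Prom1, Rian, Mirg, Dlk1, Phlda2, BC023105, Gm4951, Iigp1, the genes of the added epithelial list other than Vil1, and Cyp7a1 were named after their values were seen.

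Alternatives fixed before the data were examined were a trended or robust prior, array weights, renewed quantile normalization, median centring, 2 filters on dim genes (genes at or above the median level, 9097, and a group mean of at least 6, 8882 genes), the mean of all probe sets, leaving out probe sets that end in _x_at or _s_at, every probe set on its own, an adjusted p under 0.01, a fold of at least 2 and leaving out each array. Leaving out KO-03 and WT-104 together, the arrays nearest the other genotype on the first principal component, was added after the data were seen. All 7 arrays carried Y-linked transcripts, so a sex covariate was not used. A test of miR-122 seed sites in 3' untranslated regions was planned and not run, because transcript sequences were not used here.

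The fit was tested on simulated data in 10 runs of 18193 genes with 200 changed genes. It recovered 75.2% of genes changed by 1 and 95.9% of genes changed by 2 on the log2 scale, and 5.14% of calls were false. The simulated genes were drawn independently of each other, unlike real genes, so these shares need not hold for the real calls. Permutations over genes used 100000 draws. Scripts also used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.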

Results

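Livers of 2-month-old mice of mixed genetic background were profiled on Affymetrix mouse expression arrays, with 4 miR-122 knockout animals (KO-03, KO-90, KO-91 and KO-94) and 3 wild-type animals (WT-27, WT-103 and WT-104), 1 array per animal. miR-122 is the most abundant microRNA of hepatocytes, and the comparison asks which liver transcripts differ when it is absent. The values were log2 expression values of 45101 probe sets, which gave 18193 named genes. Array medians lay between 4.65 and 4.72, and the number of arrays limits the precision. Pearson correlations across genes were 0.989 to 0.991 within wild type, 0.979 to 0.992 within knockout and 0.969 to 0.988 between genotypes. The first principal component held 48.6% of the variance and placed WT-27, WT-103 and WT-104 at -32.3, -31.1 and -20.1, KO-03 at -1.32, and KO-91, KO-90 and KO-94 at 15.8, 26.5 and 42.5. No probe set named here reports miR-122 itself, so the genotype labels could not be checked against the deleted gene. The Y-linked gene Eif2s3y averaged 8.84 ± 0.26 (SD, n = 3) in wild type and 8.19 ± 0.44 (SD, n = 4) in knockout, and Xist averaged 5.26 ± 0.40 (SD, n = 3) and 5.32 ± 0.23 (SD, n = 4).

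More liver transcripts were higher than lower in miR-122 knockout: 470 genes were higher in knockout and 173 were lower. The largest measured rises included the fetal growth factor Igf2, from 6.44 ± 0.22 (SD, n = 3) to 11.75 ± 1.32 (SD, n = 4), a 39.5-fold difference (its second probe set differed by at least 1.14 on the log2 scale), and the cytochrome P450 gene Cyp2b9, which was at least 32.8-fold higher. The long noncoding RNA Meg3 rose by 3.89, the iron-binding secreted protein Lcn2 by 3.67, Cdc42ep5 by 3.62 and Cyp2b13 by at least 3.42 on the log2 scale. The lysophospholipid transporter Mfsd2a rose by 3.47, asparagine synthetase Asns by 3.37, the calcium-binding protein S100a8 by at least 3.25 and the microvillus protein villin, Vil1, by at least 2.26 on the log2 scale. Cyp2b9 and Cyp2b13 are near-identical paralogs, so their separate values are uncertain. The largest falls were in the glucuronosyltransferase Ugt2b38, from 8.74 ± 0.58 (SD, n = 3) to 4.35 ± 0.35 (SD, n = 4), a difference of at least 3.73. Next came the fatty acid elongase Elovl3 (-3.56), the aminotransferase Kyat3 (-2.68), Fam47e (a fall of at least 2.10) and Nxpe2 (at least 2.17). Falls followed in the adenylate kinase Ak4 (-2.29), the sulfotransferase Sult5a1 (-2.10), the acetyl-CoA carboxylase Acacb (-1.98), the amylase Amy1 (-1.82) and Zfand4 (-1.80). Detection calls were not given in the values used, so the highest of 27 bacterial control probe sets, 4.71 to 5.23 per array, was taken as a floor for levels, and "at least" marks differences against that floor. Every array of the dimmer genotype lay at or under it for Vil1, Ugt2b38, Tspan8 and Atf3. So did 2 of 3 wild-type arrays for Cyp2b9, Cyp2b13, Krt19 and Epcam, 1 of 3 for S100a8, Col1a1 and Cd24a, and 1 of 4 knockout arrays for Fam47e and Nxpe2. Albumin, Alb, stayed at 14.60 ± 0.04 (SD, n = 3) and 14.63 ± 0.04 (SD, n = 4), with an adjusted p of 0.901 in limma.

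These counts came from limma at an adjusted p under 0.05, and 2981 genes had an unadjusted p under 0.05. In all 643 called genes every knockout array lay on one side of every wild-type array, as it did in 15.8% of all genes, where chance gives 5.71%. The higher count moved to 216, 132 and 243 without WT-27, WT-103 and WT-104, to 892, 251 and 230 without KO-03, KO-90 and KO-91, and to 724 without KO-03 and WT-104 together. The lower count moved to 68, 37 and 53 without WT-27, WT-103 and WT-104 and to 93, 62 and 108 without KO-90, KO-91 and KO-94, and all 643 genes kept their sign in each of these 7 fits that left out 1 array. Among the 20 genes with the largest changes, Meg3 (without WT-103), S100a8 (WT-27 or WT-103), Nxpe2 (WT-103 or WT-104), Acacb (WT-103), Fam47e (each wild type, KO-90 or KO-91) and Sult5a1 (WT-103 or WT-104, KO-90, KO-91 or KO-94) lost their call. Their adjusted p reached 0.0554, 0.0636, 0.0678, 0.0628, 0.186 and 0.141. Of the named called genes, 37 had several probe sets, with 82 beside those used. Of these 82, 20 lay at or under the floor on all 7 arrays. Such a level does not rule out signal. The second probe set of Gys1, among these 20, rose by 0.87 (limma adjusted p = 0.0181 over all probe sets). The median of the 27 control probe sets, 2.86 to 3.14 per array, lay well below the floor. On every array the floor was set by the same control probe set, AFFX-PheX-3_at. The other controls lay lower, among them AFFX-r2-Bs-thr-M_s_at at 3.57 to 4.11. Of the other 62, 59 differed in the direction of the one used, and 3 in the opposite direction, 1 each of Cdc42ep5 (-0.03), Epcam (-0.17) and Sox4 (-0.15). With the mean of all probe sets of a gene, those under the floor included, 17 of the 37 differences were over 1.5 times smaller. Others were larger, among them Fmo2 (1.69, against 1.07 with the one used) and Klf6 (1.02 against 0.77). With that mean Hand2 and Slc1a2 lost their calls (limma adjusted p = 0.138 and 0.185). Fam47e lost its call in the same fit (limma adjusted p = 0.0530), although it has a single probe set, whose values did not change. Fmo2 lost its call with median centring, Pgk1 with renewed quantile normalization and Fam47e with a robust prior. In 9 of 174 genes and list means, about the number chance gives, 1 knockout array stood apart. Of those reported here, it was KO-03 for Mttp, Ccl9 and Tspan8 and KO-94 for the means of the cell cycle and acute phase lists.

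**Figure D1:**
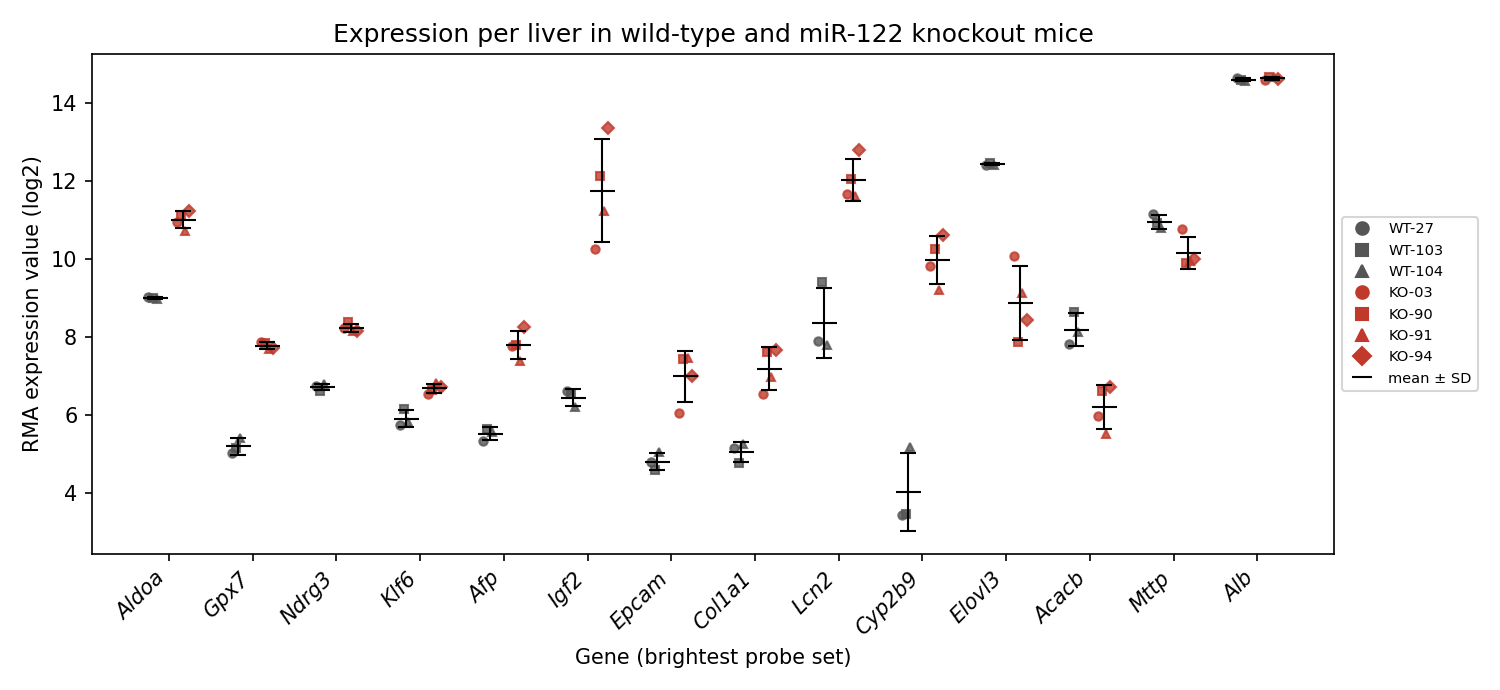
Log2 RMA expression value (vertical axis) of 14 genes (horizontal axis) in each of 3 wild-type livers (grey) and 4 miR-122 knockout livers (red), with black bars for mean ± SD. Aldoa moved from 9.01 to 11.01 with little spread, Igf2 varied widely between knockout animals (SD 1.32), and Alb stayed at 14.60 and 14.63.

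Published targets of miR-122 were higher as a group in the knockout. Of 37 measured targets, 17 rose, 0 fell and 20 did not pass, and 25 rose when adjusted over the list alone. The peroxidase Gpx7 rose from 5.20 ± 0.21 (SD, n = 3) to 7.78 ± 0.08 (SD, n = 4) and aldolase A, Aldoa, from 9.01 ± 0.03 to 11.01 ± 0.23. Ndrg3 rose by 1.51 ± 0.11 (SE) and the secretory pathway protein Tmed3 by 1.84 ± 0.18 (SE). The transcription factor Klf6 rose by 0.77 ± 0.13 (SE), with an adjusted p of 0.0171 that reached 0.0725 when WT-27 or WT-104 or KO-91 was left out. Other probe sets of Klf6 rose by more, by 1.53 and by at least 1.08 and 0.90. The remaining probe set of Klf6 lay at or under the floor on all arrays. The median of the list was 0.72 (camera adjusted p = 5.25e-22, adjusted p = 0.103 with an estimated correlation), and the exact permutation p of its mean was 0.0286, the smallest that 35 splits allow. Klf6 and Ccn2 may have entered the list through work on this knockout, so they are not independent evidence of its direction.

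Extracellular matrix genes had as many rises as the published targets. Of 33 measured members, 17 rose, 0 fell and 16 did not pass, and 26 rose when adjusted over the list alone. Collagen Col1a1 rose from 5.06 ± 0.26 (SD, n = 3) to 7.19 ± 0.54 (SD, n = 4), by at least 2.09. Col6a3 rose by 1.46 ± 0.13 (SE), the proteoglycan Lum by 1.69 ± 0.20 (SE) and the collagen prolyl hydroxylase P4ha1, which is also on the target list, by 1.46 ± 0.16 (SE). The list median was 0.94 (camera adjusted p = 4.34e-22, adjusted p = 0.166 with an estimated correlation), with an exact permutation p of 0.0286. Among 13 markers of hepatic stellate cells, the matrix-producing cells of the liver, 4 rose, 0 fell and 9 did not pass (5 rose when adjusted over the list alone). They were led by the growth factor receptors Pdgfra at 1.41 ± 0.15 (SE) and Pdgfrb at 1.03 ± 0.15 (SE), with Dcn at 0.90 and Hand2 at 1.09. The stellate list had a median of 0.36 (camera adjusted p = 4.38e-05, adjusted p = 0.144 with an estimated correlation) and an exact permutation p of 0.0286. Dcn, Pdgfrb and Hand2 lost their calls without single arrays, at adjusted p up to 0.0732 (WT-27 or WT-103 left out), 0.0530 (WT-103) and 0.164 (any array but KO-03).

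Oncofetal and progenitor genes were higher in knockout. Of 15 measured members, 6 rose, 0 fell and 9 did not pass, and 8 rose when adjusted over the list alone. The serum protein of fetal liver Afp rose from 5.52 ± 0.16 (SD, n = 3) to 7.80 ± 0.36 (SD, n = 4). The transcription factor Sox4 rose by 3.03 ± 0.24 (SE), but the only other of its 8 probe sets above the floor on all 7 arrays differed by 0.92. Further rises were in the surface protein Cd24a by at least 2.73 and in Igf2 by 5.30 ± 0.59 (SE). Of the other 4 probe sets of Afp, 2 differed by at least 2.73 and 0.39 and 2 lay at or under the floor on all arrays. The list median was 0.69 (camera adjusted p = 1.65e-08, adjusted p = 0.242 with an estimated correlation), with an exact permutation p of 0.0286. Of 9 cholangiocyte markers, genes of bile duct cells, 4 rose, 0 fell and 5 did not pass (6 rose when adjusted over the list alone). These were Cd24a, Tspan8 by at least 1.70 on the log2 scale, the adhesion molecule Epcam by at least 2.06 and the keratin Krt19 by at least 1.10. That list had a median of 0.68 (camera adjusted p = 1.70e-06, adjusted p = 0.242 with an estimated correlation), and the exact permutation p of its mean was 0.0571. Of the other 4 probe sets of Tspan8, 3 lay at or under the floor on all arrays and 1 differed by at least 0.24, and the second of Epcam differed by -0.17. Epcam lost its call without WT-103 (adjusted p = 0.0556) and Krt19 without any array but KO-03 (adjusted p up to 0.109).

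**Figure D2:**
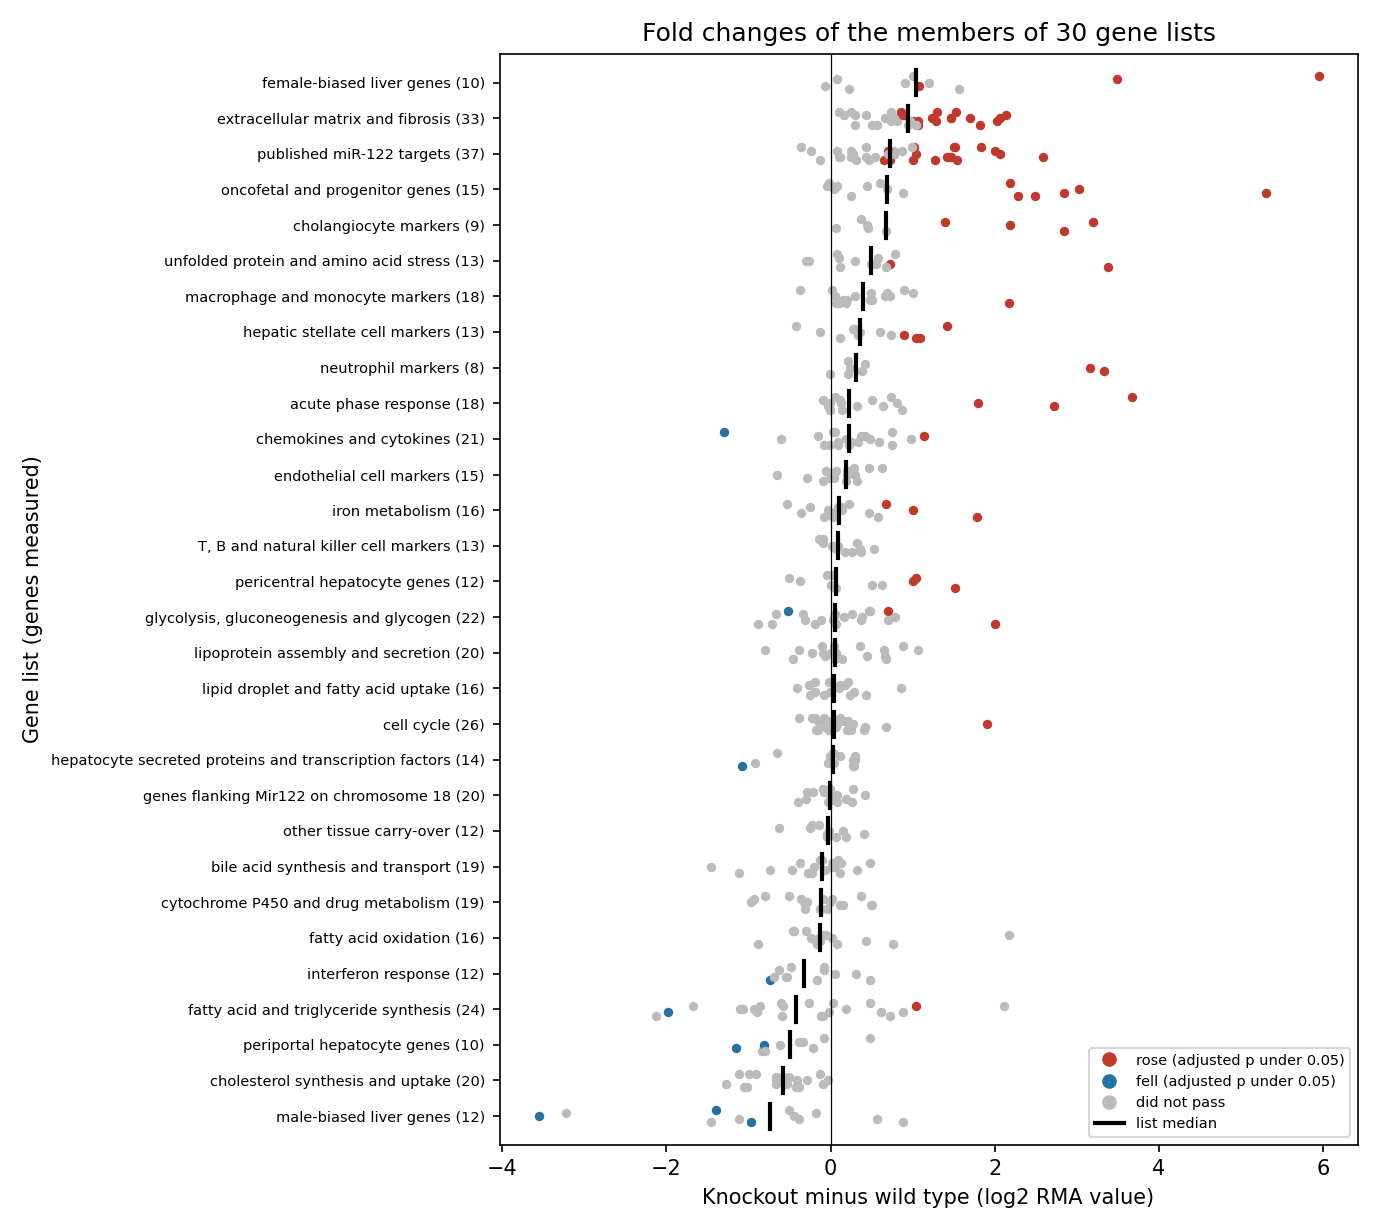
Log2 difference between knockout and wild type (horizontal axis) of each measured member of 30 gene lists (vertical axis, number of genes measured in parentheses), red where the gene rose, blue where it fell and grey where it did not pass an adjusted p under 0.05, with a black bar at the list median. In the target and matrix lists 17 genes each rose and 0 fell, while the cholesterol list had a median of -0.58 with 0 members past the test.

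Genes of lipid synthesis had lower medians with few single calls. None of 20 cholesterol synthesis and uptake genes passed the test (0 rose, 0 fell, also when adjusted over the list alone), with Pmvk at -0.99 ± 0.28 (SE), Dhcr7 at -1.27 ± 0.37 (SE) and Fdps at -1.12 ± 0.47 (SE), all enzymes of sterol synthesis. Pmvk and Dhcr7 each passed in 2 of 20 alternatives, with limma adjusted p down to 0.0236 and 0.0211 when 1 array was left out. The list median was -0.58 (camera adjusted p = 6.06e-06, adjusted p = 0.521 with an estimated correlation), the exact permutation p of its mean was 0.171, and the list mean of KO-90 lay 0.19 above the wild-type mean. Of 24 fatty acid and triglyceride synthesis genes, Agpat1, an acyltransferase also on the target list, rose by 1.04 ± 0.11 (SE), Acacb fell by 1.98 ± 0.30 (SE) and 22 did not pass, and 2 rose and 11 fell when adjusted over the list alone. Its median was -0.42 (camera adjusted p = 0.00693, adjusted p = 0.437 with an estimated correlation; exact permutation p = 0.0571). Among those that did not pass, Acly was at -1.10 and Fads2 at 0.61 (limma adjusted p = 0.058 and 0.053). They passed in 4 and 5 of 20 alternatives. Another probe set of Acly, at -1.61, passed over all probe sets (limma adjusted p = 0.0198), and its others did not, with a dim one at 0.10. Other probe sets of Fads2, at 0.65 and 0.55, passed there too (0.0449 and 0.0350). The lipid transfer protein Mttp, needed for lipoprotein assembly, was 10.96 ± 0.18 (SD, n = 3) in wild type and 10.16 ± 0.41 (SD, n = 4) in knockout and did not pass (adjusted p = 0.0875). Mttp passed in 3 of 20 alternatives, and its limma adjusted p fell to 0.00386 in a fit that left out 1 array. In the lipoprotein (20 genes), lipid droplet and fatty acid uptake (16) and fatty acid oxidation (16) lists 0 genes passed and the camera adjusted p was 0.500, 0.775 and 0.184. Adjusted over the list alone 3 rose and 2 fell, 0 and 0, and 0 and 0. The fatty acid transporter Cd36 differed by -0.25 ± 0.25 (SE). The median of the oxidation list was -0.14 and its mean 0.02. Of 19 bile acid genes 0 passed and 1 fell when adjusted over the list alone (median -0.11, camera adjusted p = 0.0463, adjusted p = 0.545 with an estimated correlation; exact permutation p = 0.371), a call lost in 13 of 21 alternatives.

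**Figure D3:**
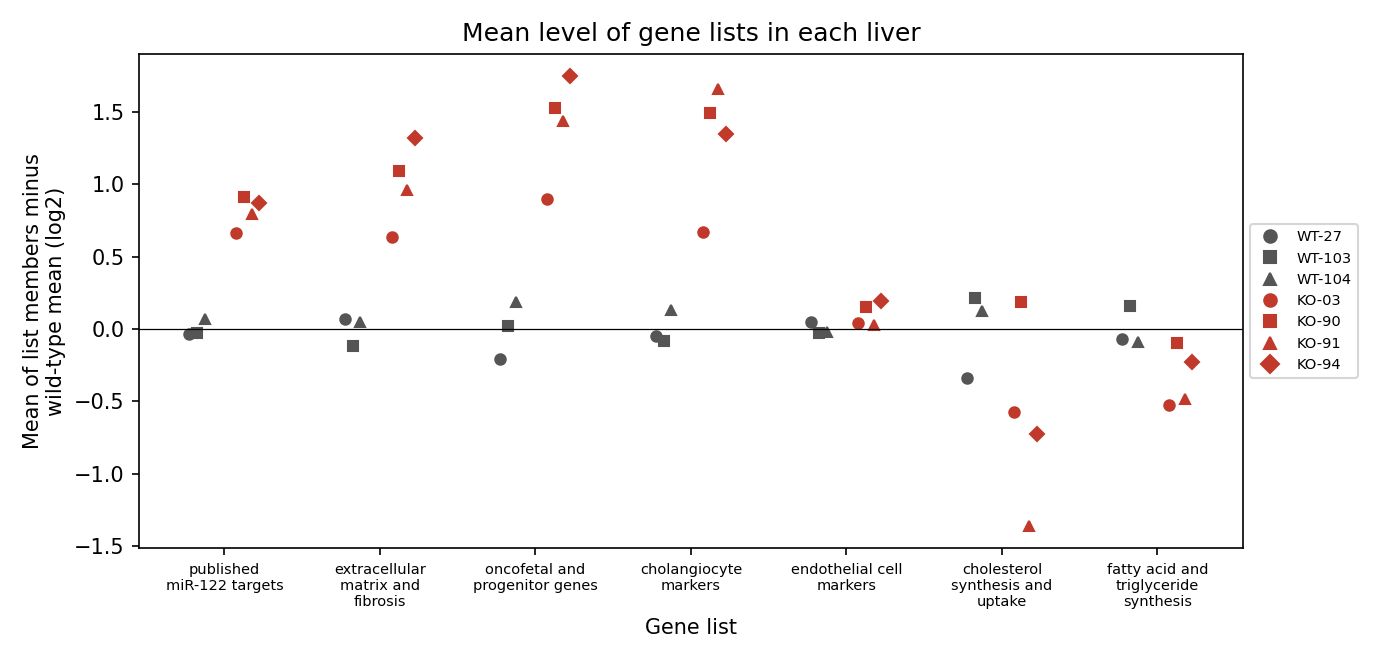
Mean log2 level of 7 gene lists (horizontal axis) in each of 3 wild-type (grey) and 4 knockout (red) livers, relative to the wild-type mean (vertical axis). The knockout livers lie above the wild-type livers for the target list, where KO-03 is at 0.66 and KO-90 at 0.91, while for the cholesterol list KO-90 is at 0.19 and KO-91 at -1.36.

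Female-biased liver genes were higher and male-biased ones lower, in arrays that all carried Y-linked transcripts. Of 10 female-biased genes 3 rose, 0 fell and 7 did not pass (5 rose when adjusted over the list alone). They were Cyp2b9, Cyp2b13 and the monooxygenase Fmo2 at 1.07 ± 0.24 (SE). Of 12 male-biased genes 0 rose, 3 fell and 9 did not pass (8 fell when adjusted over the list alone). They were Elovl3, Cyp2u1 at -1.39 ± 0.18 (SE) and the fatty acid hydroxylase Cyp4a12a at -0.97 ± 0.21 (SE). The list medians were 1.03 (camera adjusted p = 5.64e-05, adjusted p = 0.166 with an estimated correlation) and -0.74 (camera adjusted p = 6.06e-06, adjusted p = 0.175 with an estimated correlation), with exact permutation p of 0.0286 and 0.0571. Fmo2 and Cyp4a12a lost their calls without any array but KO-03, at adjusted p up to 0.175 and 0.140. Other probe sets of Fmo2 rose by more, by 2.67, 2.11 and at least 2.37, and its remaining probe set lay at or under the floor on all arrays. Of 10 periportal genes 0 rose, 2 fell and 8 did not pass (5 fell when adjusted over the list alone). They were the urea cycle enzyme Asl at -0.81 ± 0.15 (SE) and the histidine-degrading enzyme Hal at -1.15 ± 0.23 (SE). The list median was -0.50 (camera adjusted p = 9.44e-05, adjusted p = 0.166 with an estimated correlation; exact permutation p = 0.0286). Of 12 pericentral genes 3 rose, 0 fell and 9 did not pass (4 rose when adjusted over the list alone). They were the aminotransferase Oat at 1.03 ± 0.12 (SE), Lhpp at 1.01 ± 0.19 (SE) and the glutamate transporter Slc1a2 at 1.52 ± 0.32 (SE). The list median was 0.06 (camera adjusted p = 0.0468, adjusted p = 0.545 with an estimated correlation; exact permutation p = 0.0857). That call was lost in 10 of 21 alternatives, among them fry (adjusted p = 0.136), ranks (0.185), filters on dim genes (0.106 and 0.118) and fits without WT-27, KO-03 or KO-90 (up to 0.119). Asl, Hal, Lhpp and Slc1a2 each lost the call without any of 5 single arrays, at adjusted p up to 0.0931, 0.138, 0.112 and 0.129.

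Markers of immune cells and of inflammation moved in a few members. Of 18 macrophage markers, the endotoxin receptor Cd14 rose by 2.17 ± 0.42 (SE), 0 fell and 17 did not pass. Adjusted over the list alone, 3 rose (list median 0.39, camera adjusted p = 0.00165, adjusted p = 0.536 with an estimated correlation). Of 8 neutrophil markers, S100a8 and S100a9, at 3.16 ± 0.54 (SE), rose, 0 fell and 6 did not pass, with the same numbers adjusted over the list alone (median 0.30, camera adjusted p = 0.00507, adjusted p = 0.448 with an estimated correlation). Of 18 acute phase genes, Lcn2, Orm2 at 2.72 ± 0.51 (SE) and Orm3 at 1.80 ± 0.36 (SE) rose, 0 fell and 15 did not pass. Adjusted over the list alone, 4 rose (list median 0.22, camera adjusted p = 0.00316, adjusted p = 0.584 with an estimated correlation). The list mean of KO-94 lay 1.38 above wild type and those of the other knockouts 0.40 to 0.49, and the list lost its call without WT-104 (adjusted p = 0.0686) and with fry (0.227). Of 13 genes of the unfolded protein and amino acid stress responses, Asns and the transcription factor Atf3, by at least 0.61, rose, 0 fell and 11 did not pass. Adjusted over the list alone, 3 rose (list median 0.49, camera adjusted p = 0.00316, adjusted p = 0.172 with an estimated correlation). Of 12 interferon response genes, the antiviral gene Rsad2 fell by 0.74 ± 0.14 (SE) and 11 did not pass. Adjusted over the list alone, 3 fell (list median -0.32, camera adjusted p = 0.00693, adjusted p = 0.448 with an estimated correlation). The exact permutation p of the list means was 0.114, 0.0571, 0.0286, 0.0286 and 0.143 in that order. Among 21 chemokines and cytokines Cxcl12 rose by 1.14 ± 0.17 (SE) and Ccl9 fell by 1.30 ± 0.27 (SE), as also when adjusted over the list alone (camera adjusted p = 0.0848). Of these genes Cd14, S100a9, Orm2, Orm3, Atf3, Rsad2, Ccl9 and Cxcl12 lost their calls without at least 1 single array, at adjusted p up to 0.137, 0.0831, 0.0992, 0.113, 0.128, 0.116, 0.159 and 0.0551.

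The other lists did not pass the list test. In the iron list (16 genes) the target Hjv, a regulator of hepcidin, rose from 9.51 ± 0.06 (SD, n = 3) to 10.51 ± 0.15 (SD, n = 4). The hepcidin genes Hamp2 and Hamp, which are close paralogs, rose by 1.78 ± 0.33 (SE) and 0.67 ± 0.15 (SE). In this list 0 fell and 13 did not pass (3 rose when adjusted over the list alone, camera adjusted p = 0.213). In the carbohydrate list (22 genes) Aldoa and glycogen synthase Gys1 at 0.69 ± 0.14 (SE), both on the target list, rose, and the glycolytic enzyme Pgk1 fell by 0.52 ± 0.11 (SE). Adjusted over the list alone 4 rose and 4 fell (camera adjusted p = 0.654). Hamp2, Hamp, Gys1 and Pgk1 lost their calls without at least 1 single array, at adjusted p up to 0.0986, 0.175, 0.107 and 0.151. Hamp lost it also after renewed quantile normalization or median centring. Without probe sets that end in _x_at or _s_at both hepcidin genes lost it (adjusted p = 0.723 and 0.0690). The second probe set of Hamp2, used there, lay at or under the floor on all arrays, so whether it bears on the rise is open. Of 26 cell cycle genes the cyclin Ccnd1 rose by 1.90 ± 0.18 (SE) and 25 did not pass (1 rose when adjusted over the list alone, camera adjusted p = 0.491). Of 14 hepatocyte genes the transcription factor Foxa2 fell by 1.08 ± 0.21 (SE) and 13 did not pass (1 fell when adjusted over the list alone). The list had a median of 0.03, a mean of -0.08 and a camera adjusted p of 0.931. Foxa2 lost its call without any of 5 single arrays (adjusted p up to 0.128). In the endothelial (15 genes), T, B and natural killer cell (13), Mir122 neighbourhood (20, of which Relch lies on chromosome 1, away from Mir122) and other tissue (12) lists 0 genes passed, also when adjusted over the list alone, and camera adjusted p was 0.221, 0.304, 0.667 and 0.446. In the neighbourhood list 1 of the 5 probe sets of Lman1, not the one used, passed (adjusted p = 0.0342 over all probe sets), with a fall of at least 0.48 to a level under the floor on all knockout arrays. In the list of 19 cytochrome P450 and drug metabolism genes 0 passed, 2 rose and 3 fell when adjusted over the list alone, and camera adjusted p was 0.109.

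Of the 30 lists tested, 17 passed camera with its preset correlation, 11 upward and 6 downward. With an estimated correlation 0 passed (camera in limma, lowest adjusted p = 0.103) and 7 had an unadjusted p under 0.05. The exact permutation p of the list mean was under 0.05 in 8 of the 30 lists and 0.107 in each of these after adjustment over the 30 lists, and the other 34 splits of the arrays gave a median of 9 lists past camera.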

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

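All tests of explanations in this part were chosen after the result was seen, except the counts over other splits of the arrays for the higher genes, the lower genes and the lists. The count over splits for both directions together was added after the split counts for single directions were seen.

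Among the 35 splits of the 7 arrays into 4 and 3, only the real one gave 470 genes higher in the group of 4. The highest other count was 46, so chance is unlikely for the 470. It is not excluded, since 1 of 35 is the smallest share these splits can give. The split of KO-90, KO-91 and KO-94 against the rest, which gave the 46, called 319 in the opposite direction, also fewer than 470. For genes lower in the group of 4, 2 of the 35 splits gave as many (173, highest other 319), so by this count chance is not excluded for the lower genes taken alone. In that split the group of 4 holds the wild types and KO-03, so its 319 genes are higher in the other 3 knockouts, and 46 are lower in them. The doubt therefore comes from a split close to the real one turned round, and points to a structure of the samples in which KO-03 lies between the genotypes. With both directions together, 1 of the 35 splits gave as many calls (643, highest other 365). For lists past camera, 1 of 35 gave as many (17), but the highest other split, WT-103 and WT-104 with KO-03 against the rest, gave 16.

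The extracellular matrix list had a median of 0.98 over its 22 members with a wild-type level of 6 or more. For a given probe set this filter does not depend on the knockout values. The probe set of each gene was chosen by its mean over all arrays, knockouts included. A rise in knockout can therefore still affect which wild-type level was filtered. A lower share of hepatocytes would raise the markers of other cells alike, and the endothelial median over 11 genes was 0.18, a difference of 0.800 (two-sided permutation p over genes = 0.00166). More stellate cells in an unchanged state would raise stellate markers as much. Dcn, which is on both lists, was counted as a matrix gene only. The median over 10 stellate markers outside the matrix list was 0.47, a difference of 0.517 (permutation p over genes = 0.0298). Without the level filter, with Dcn still on the matrix side only, the differences were 0.757 and 0.591 (permutation p over genes = 0.00091 and 0.00868). Genes are not independent replicates, so both p-values are too small by an unknown amount. A change of state of matrix-producing cells, or more cells of a kind without a list here such as portal fibroblasts, may account for the rise and was not tested.

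KO-03 lay nearer the wild types than the other knockouts did, on the first principal component. Over genes called without that array, its median position on the way from the wild-type mean to the mean of the other knockouts was 84.9% for 22 published targets and 56.0% for 35 other matrix, progenitor, cholangiocyte and stellate genes, a difference of 28.9 points (permutation p over genes = 0.0014, and 0.00094 on the linear scale with medians of 77.4% and 39.5%). Wild-type RNA mixed into that sample, or a loss of contrast over the whole array, would shift both sets alike. The same difference, targets minus the other genes, was -6.78 points for KO-90, -1.67 for KO-91 and -30.9 for KO-94, so KO-03 alone had a positive difference, while that of KO-94 was as large in the opposite direction. Deviations of this size thus also occur in a knockout without such a shift toward wild type, and genes are not independent replicates. Mixed RNA, a loss of contrast and a milder or later secondary response in that animal cannot be told apart.

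BC023105 rose by 2.98 and Gm4951 fell by 1.41 on the log2 scale (Gm4951 lost its call without WT-27, WT-103, WT-104 or KO-90, at adjusted p up to 0.141, and without KO-03 and WT-104 together). On chromosome 18, which also carries Mir122, 1 measured gene lies between them. Mice of mixed background could carry a stretch of the other strain around the targeted allele. Of the 100 measured genes nearest Mir122, 6 were called, against a median of 3 and a maximum of 9 over 1614 windows of 100 genes, and 83.4% of the windows had fewer. Counting genes with any probe set past the test, among them Lman1, 5 were called near Mir122 against a median of 3 and a maximum of 8, and 80.7% of the windows had fewer. Both counts hold BC023105, and the first also holds Gm4951. Their changes prompted the test, so neither count is independent of them. BC023105 has rank 78 by distance to Mir122 among the measured genes of chromosome 18. Both counts lie between the bounds set for and against a strain stretch, so the stretch and another origin cannot be told apart. BC023105 moved against the interferon list, which had a median of -0.32, and Gm4951 moved with it. Only 1 of the 12 interferon genes was called, and the exact permutation p of the list mean was 0.143. A list this weak cannot decide whether a change of the interferon response accounts for either gene.

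Among the 4 knockout arrays, 1 array stood apart from the other 3 in 9 of 174 genes and list means examined, where chance alone gives about 1 in 20. KO-03 stood apart for Mttp (10.77, others 9.90 to 9.99), Ccl9 (8.646, others 9.71 to 9.89) and Tspan8 (5.301, others 6.93 to 7.23). KO-91 stood apart for Fads2 (10.41, others 10.86 to 10.91). KO-94 stood apart for Serpina3n (12.25, others 11.55 to 11.57), Ccbe1 (6.521, others 5.82 to 5.90), Cela1 (8.991, others 9.70 to 9.83), the mean of the cell cycle list (0.4308 above wild type, others 0.01 to 0.04) and the mean of the acute phase list (1.379, others 0.40 to 0.49). Outside the named genes, 50 of 10092 probe sets without a single gene name passed the test, 41 of them higher and 9 lower in knockout.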

How the results depend on the processing

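The joint omission of KO-03 and WT-104 was added after the data were seen, and the other settings were planned. No direction of a called count, list or named gene reversed under any setting run. The cause of a changed count or call was not tested, except that stricter thresholds lower the number of calls by construction. Genes higher and lower numbered 909 and 344 with array weights, 141 and 31 at an adjusted p under 0.01 and 258 and 66 at a fold of at least 2, and 724 were higher without KO-03 and WT-104. Leaving out 1 array gave 132 to 892 higher and 37 to 252 lower genes. All other settings stayed within 1.5 times the main counts. Median centring and renewed quantile normalization moved the median of all genes by 0.006 and -0.012. Of 67 named genes past the test, 33 kept the call in each fit that left out 1 array and 34 lost it in at least 1. This count, and that of named genes with several probe sets, leave out Lad1, Pls1, Cldn7, Elf3, Spint1, Myo5b, Marveld3 and Phlda2, named for lists added later.

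List results are adjusted p. With an estimated correlation 17 lists lost their call: published miR-122 targets (0.103), cholesterol synthesis and uptake (0.521), fatty acid and triglyceride synthesis (0.437), bile acid synthesis and transport (0.545), extracellular matrix and fibrosis (0.166), hepatic stellate cell markers (0.144), macrophage and monocyte markers (0.536), neutrophil markers (0.448), oncofetal and progenitor genes (0.242), cholangiocyte markers (0.242), female-biased liver genes (0.166), male-biased liver genes (0.175), interferon response (0.448), acute phase response (0.584), unfolded protein and amino acid stress (0.172), pericentral hepatocyte genes (0.545), periportal hepatocyte genes (0.166).
With fry 8 lists lost it: cholesterol synthesis and uptake (0.285), fatty acid and triglyceride synthesis (0.222), bile acid synthesis and transport (0.508), macrophage and monocyte markers (0.216), neutrophil markers (0.135), interferon response (0.174), acute phase response (0.227), pericentral hepatocyte genes (0.136).
Without KO-03 and WT-104 the lost calls were bile acid synthesis and transport (0.0544), neutrophil markers (0.143), acute phase response (0.122), unfolded protein and amino acid stress (0.143), pericentral hepatocyte genes (0.122), and those gained were fatty acid oxidation (0.0035), cytochrome P450 and drug metabolism (0.0165).
The bile acid list also lost its call with array weights (0.347), renewed quantile normalization (0.113), only genes at or above the median level (0.0857), a group mean of at least 6 (0.0864), every probe set (0.0628), the threshold of 0.01 (0.0463) and the rank version of camera (0.0564). The pericentral list lost it with only genes at or above the median level (0.106), a group mean of at least 6 (0.118), the threshold of 0.01 (0.0468) and ranks (0.185). The chemokine list gained a call with every probe set (0.028).
Leaving out 1 array changed calls of these lists, given with the lowest and highest adjusted p: bile acid synthesis and transport (0.00862 to 0.72; WT-27, WT-104, KO-94), pericentral hepatocyte genes (0.00527 to 0.119; WT-27, KO-03, KO-90), fatty acid oxidation (0.00856 to 0.667; WT-103, KO-03), acute phase response (0.000179 to 0.0686; WT-104), cytochrome P450 and drug metabolism (0.0164 to 0.792; KO-03), chemokines and cytokines (0.0205 to 0.524; KO-91, KO-94). The robust prior and the fold threshold gave no list results, the sex covariate and the seed site test were not run, and signal over background was not given in the values used.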

Other observations

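The added lists and their tests in this part were chosen after the data were seen. Genes of epithelial junctions and the brush border, the microvillus surface of absorptive epithelia, were higher in knockout: of 22 measured members 8 rose and 0 fell, with a median of 0.68 (camera p = 3.38e-12, p = 0.0202 with an estimated correlation). Besides Vil1, the actin-bundling protein Pls1 rose by at least 2.91, the anchoring filament protein Lad1 by 2.37 ± 0.22 (SE) and the tight junction protein Cldn7 by at least 1.46 on the log2 scale, against the highest bacterial control probe set, which 1 of 3 and 3 of 3 wild-type arrays did not exceed for Pls1 and Cldn7. Cldn7 lost its call without any array but KO-03 (adjusted p up to 0.167). Elf3, Spint1 and Marveld3 also lost theirs without single arrays, at adjusted p up to 0.0959, 0.0847 and 0.163. Without WT-103, and without WT-104, Cldn7 and these genes all lost it. Vil1, Lad1, Pls1 and Myo5b kept the call in each such fit. The list of cholangiocytes, another epithelial cell type, moved the same way (median 0.68, 4 of 9 rose). The junction list was written with some of these genes already seen, so its p-values are not independent evidence.

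Of 23 measured imprinted genes, 5 rose and 0 fell (median 0.32, camera p = 5.54e-05, p = 0.00668 with an estimated correlation), and this list too was written after Igf2 and Meg3 were seen. Beside Igf2 and Meg3 the noncoding RNAs Rian and Mirg rose by at least 2.16 and 2.43, and Phlda2 by at least 0.52, against the same floor. It was reached or undercut on 3, 1 and 3 of the 3 wild-type arrays. Rian lost its call without WT-103 (adjusted p = 0.0514), Mirg without any single wild type (adjusted p up to 0.0689) and Phlda2 without WT-27, WT-104 or KO-90 (up to 0.0725). Dlk1, which is expressed from the other parental copy of the Meg3 locus, lay under the floor on all 7 arrays, so no difference is given for it. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.09 ± 1.43 (SE), with an SD of 2.75 (n = 3) in wild type and 2.34 (n = 4) in knockout. The interferon-inducible GTPase Iigp1 was at 12.15 ± 0.09 (SD, n = 3) and 11.47 ± 0.36 (SD, n = 4) and did not pass (adjusted p = 0.0938).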
